A study of Homo sapiens with 36 samples.

How the data were processed

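Polyadenylated RNA was sequenced from MIA PaCa-2, a human pancreatic cancer cell line, carrying doxycycline-inducible Cas9 with a guide against PELO, a guide against HBS1L, or a non-targeting control guide (NTC). The aim named in the series record is to learn what loss of PELO or HBS1L does in cells whose SKI complex is destabilised. PELO and HBS1L form the complex that splits ribosomes stalled on messenger RNA, and the SKI complex feeds such messengers to the RNA exosome. Cells of each of the 3 guide lines were grown with or without doxycycline (dox) and taken at 48 h or 96 h. Each of the 12 groups holds 3 libraries, 36 in all.

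Per the submitters' processing notes, DRAGEN, featureCounts, Subread, edgeR and limma were used with the human genome build GRCh38.p13; their versions, order, options and gene annotation are not given in the sources used here. The deposited count table holds expected counts, that is fractional read counts per Ensembl gene, in 1 column per library. Fractions were seen in the values: 45.6% of the values above 0 were not whole numbers. Such fractions arise when a read that fits several genes or places is shared among them. The second table of the authors holds log2 CPM: each log2 value equals the log2 of the count plus 0.5, plus 1 constant per library, with a largest deviation of 5.2e-14. It lists 17138 of the 61544 genes in the count table, and 55 of the 8114 genes with a mean above 1000 counts are absent from it. For that reason the count table was used throughout, and the log2 table only as an alternative.

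Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20767 genes holding at least 99.9% of the counts of every library. Library sizes were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to the 36 libraries with robust dispersion, and each comparison was a contrast of group means tested by the quasi-likelihood F test. P-values were adjusted over the genes tested by the Benjamini-Hochberg method at 0.05. Levels are given in CPM, computed on TMM-scaled library sizes, given as mean ± SD over the 3 libraries of a group. Log2 fold changes are given ± SE. Coordinates, transcript lengths and overlaps between exons came from GENCODE 29 on GRCh38.

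The comparisons were dox against no dox within each line at each time, the response of a targeted line minus that of the control line (a response beyond the control line), the PELO response minus the HBS1L response, the change of each response between the times, and each targeted line against the control line without dox. The libraries of the 2 times carry numbers from separate blocks, so time cannot be told apart from a batch, and comparisons other than those of responses between times stayed within a time. Neither labels nor records say whether the 3 replicates were separate cultures, so p-values measure only the spread between these libraries.

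Before the data were examined, 33 lists of genes were fixed, along with the comparisons, the alternatives and the rule for naming genes. The lists cover ribosome rescue and ribosome quality control, the SKI complex with the exosome, the integrated stress response, the unfolded protein response of the endoplasmic reticulum, p53 targets, immediate early genes, interferon-stimulated genes, NF-kB targets, cytosolic and mitochondrial ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, nonsense-mediated decay factors, snoRNA host genes, translation factors, ribosome biogenesis, cholesterol biosynthesis, DNA replication with E2F targets, mitosis, histones, hypoxia with glycolysis, RAS-MAPK output, the heat shock response, the mitochondrial unfolded protein response, autophagy with lysosome genes, NRF2 targets, the BCL2 family, MYC targets, markers of epithelial, fibroblast, leukocyte and endothelial cells, and genes of chromosome band 9p21. The last list had 0 genes past the filter. The others were tested with camera of limma 3.58.1, which compares a list with the other genes, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The 576 tests were adjusted together. Each list was also tested with a correlation estimated from the data and with fry. Counts of genes past 0.05 are given after adjustment over the genes tested and, where different, adjusted over the list alone.

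Genes were named by a rule: PELO and HBS1L always; for each list past 0.05, the 3 members with the smallest adjusted p in the direction of the list; for each other list, the member with the smallest adjusted p if past 0.05; and the 6 largest rises and 6 largest falls among genes past 0.05 with a mean of at least 1 CPM, whose dox libraries all lay on one side of the no-dox libraries of the line. In the comparisons of PELO with HBS1L, of times and of untreated lines, 2 members and 4 genes were taken in place of 3 and 6. Not every gene the rule gives is printed.

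The alternatives were the size factors of DESeq2 1.42.0, no filter, a filter of 5 CPM in 3 libraries, replicate number as a block, the Wald test of DESeq2, limma voom, limma-trend on the deposited log2 values, a fit of only the groups compared, and leaving out each library. A further pair was chosen after the data were seen: a comparison of the dox libraries alone, and list tests with each library's trend on transcript length and GC content removed. The method was checked on counts simulated from the fitted group means, with each targeted line given the dox response of the control line. Changes of 1.5-fold, 2-fold and 4-fold were put into 67, 67 and 66 genes with a mean above 1 CPM. Of changes of 1.5-fold beyond the control line 71.6% to 85.1% were recovered, and of changes of 2-fold 92.5% to 98.5%. Of the calls 1.64% to 7.35% were false. Far more genes were called in the real PELO line, so these rates may not hold there.

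Totals per library ranged from 45.4 to 107.4 M counts with a median of 55.2 M, and the second highest was 66.7 M. At these depths, 3 counts correspond to 0.0298 to 0.0639 CPM in a library, the level that a count of 0 still allows. This floor covers counting error only. Reads of genes whose exons overlap, and of near-identical copies such as ribosomal protein, histone, keratin, AKR1C and HSPA1 genes, can be shared between genes, so values of such genes are less certain. The histone list holds replication-dependent histones. Only polyadenylated RNA was sequenced, so histone messengers without a poly(A) tail were not measured. No library was left out.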

Results

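PELO messenger RNA did not show which libraries had lost the gene. PELO (ENSG00000152684.11, chromosome 5, 52787940 to 52804046 on the + strand) lay at 25.2 ± 1.33 CPM without dox and 20.7 ± 0.400 CPM with dox in the PELO line at 48 h, and at 29.1 ± 1.99 and 28.3 ± 1.46 CPM at 96 h. Beyond the change of the control line this was a log2 change of -0.13 ± 0.08 (adjusted p = 0.185) at 48 h and 0.01 ± 0.08 (adjusted p = 0.916) at 96 h. The control line held 27.5 ± 0.957 and 24.7 ± 0.912 CPM at 48 h, and 27.7 ± 0.707 and 26.6 ± 0.839 CPM at 96 h; in the HBS1L line PELO ranged from 24.5 to 28.2 CPM over the group means. A guide can remove the protein without lowering the message, so loss of PELO can be neither seen nor excluded here. ITGA1 overlaps 10.9% of the exonic length of PELO, and its group means stayed at or below 0.495 CPM. It was highest with dox in the PELO line, at 0.305 CPM at 48 h and 0.495 CPM at 96 h. In every other group its mean was at most 0.0733 CPM.

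HBS1L messenger RNA fell in every dox library of the HBS1L line. HBS1L (ENSG00000112339.15, chromosome 6, 134960378 to 135103056 on the - strand) went from 105.2 ± 1.76 to 36.2 ± 0.903 CPM at 48 h and from 110.7 ± 1.98 to 33.8 ± 0.327 CPM at 96 h. The log2 changes beyond the control line were -1.67 ± 0.05 (adjusted p = 2.23e-25) and -1.77 ± 0.05 (adjusted p = 3.18e-26). Without dox, HBS1L was already lower in this line than in the control line, which held 123.3 ± 1.30 CPM at 48 h and 142.8 ± 2.05 CPM at 96 h. With dox the control line held 135.4 ± 1.28 and 148.5 ± 1.07 CPM. In the PELO line HBS1L went from 132.2 ± 1.54 to 127.4 ± 3.45 CPM at 48 h, and rose from 149.2 ± 3.87 to 221.0 ± 4.42 CPM at 96 h (log2 change beyond the control line 0.51 ± 0.04, adjusted p = 2.86e-12).

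The SKI complex genes stayed expressed, while FOCAD, whose protein stabilises that complex, was at the floor. SKIC3, the scaffold, went from 100.5 ± 5.91 to 71.5 ± 3.04 CPM in the PELO line at 48 h (log2 change beyond the control line -0.53 ± 0.07, adjusted p = 1.82e-07) and from 95.4 ± 2.64 to 63.2 ± 2.57 CPM at 96 h. The helicase gene SKIC2 went from 69.0 ± 2.21 to 53.3 ± 2.31 CPM in that line at 96 h, and SKIC8 ranged from 23.7 to 30.5 CPM over all groups. FOCAD had at most 1 count in any library, and so did CDKN2A. MTAP, the neighbour of CDKN2A on chromosome 9, had at most 2 counts. The 9p21 genes therefore had no members to test.

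**Figure D1:**
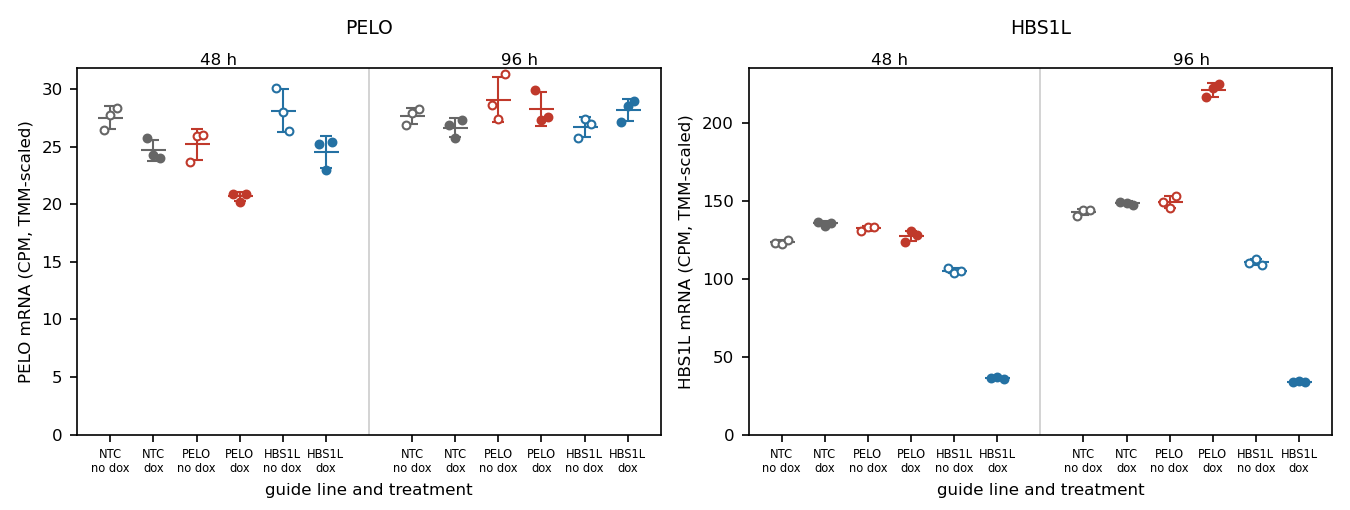
PELO (left) and HBS1L (right) messenger RNA in CPM in each library at 48 h and 96 h, with bars for the mean and SD of 3 libraries. HBS1L falls to 36.2 and 33.8 CPM with dox in the HBS1L line, while PELO in the PELO line ends at 20.7 and 28.3 CPM.

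The control line differed strongly between dox and no dox at 48 h and weakly at 96 h. Whether dox itself or another difference between the cultures gave this was not tested. At 48 h the cells without dox stood in an amino acid and stress response state that the cells with dox did not share. The genes that ATF4 drives were lower with dox, NF-kB targets were lower, and genes of DNA replication were higher. At 96 h the stress genes as a list did not differ. This background is subtracted in the comparisons beyond the control line.

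In the control line at 48 h, 7278 genes changed, 3951 up and 3327 down. Of 40 integrated stress response genes 39 fell and 1 rose (median log2 change -1.30). TRIB3, a brake on AKT induced by ATF4, went from 277.7 ± 8.14 to 49.1 ± 1.32 CPM (adjusted p = 3.90e-27), and CEBPG and CEBPB, partners of ATF4, fell by 1.38 and 1.49 on the log2 scale. FGF21 and INHBE, secreted products of the same response, fell from 1.96 to 0.0813 CPM and from 11.3 to 1.04 CPM. VEGFA fell from 163.8 to 43.1 CPM and SLC7A11, which imports cystine, from 83.2 to 16.1 CPM. Among 27 NF-kB targets 20 fell and 1 rose (21 fell adjusted over the list alone), led by RELB (log2 change -1.41), NFKB2 (-1.08) and BIRC3 (-1.16). All 37 DNA replication genes rose (median 0.63), with PCNA going from 61.6 to 136.4 CPM, MCM4 from 110.5 to 198.3 CPM and E2F2 at a log2 change of 1.20. The BCL2 family (5 rose, 13 fell) and autophagy genes (3 rose, 21 fell) shifted down, with BBC3 at a log2 change of -1.47 and MAP1LC3B at -1.05. These 5 lists held with an estimated correlation (adjusted p = 0.00206, 0.00125, 0.0138, 0.0107 and 0.0428). Nuclear-encoded oxidative phosphorylation genes rose (59 up, 2 down; adjusted p = 0.440 with an estimated correlation) and mitosis genes rose (23 up, 0 down; adjusted p = 0.339 with an estimated correlation).

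At 96 h, 1561 genes changed in the control line, 808 up and 753 down, and the integrated stress response list had 1 gene up and 4 down (median -0.00694). IFN-stimulated genes were lower (0 up, 7 down; 2 up and 14 down adjusted over the list alone; adjusted p = 0.113 with an estimated correlation). BST2, which tethers budding virus, fell from 9.25 to 5.74 CPM, and IFIT2, which binds foreign RNA, from 81.3 to 65.9 CPM. CCN1 and DUSP5, immediate early genes, rose by 0.49 and 0.64 on the log2 scale, in a list with adjusted p = 0.151 with an estimated correlation. IL1B rose from 1.07 to 2.34 CPM and PIK3CG, a kinase subunit gene, from 1.25 to 2.87 CPM, while ANK3 fell from 6.03 to 1.79 CPM and SRPX from 1.94 to 0.596 CPM. The count depended on single libraries: it was 664 without replicate 1 and 481 without replicate 2 of the control line without dox, and 992 without replicate 1 and 527 without replicate 3 with dox. The dox response of the control line differed between the times at 5496 genes.

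**Figure D2:**
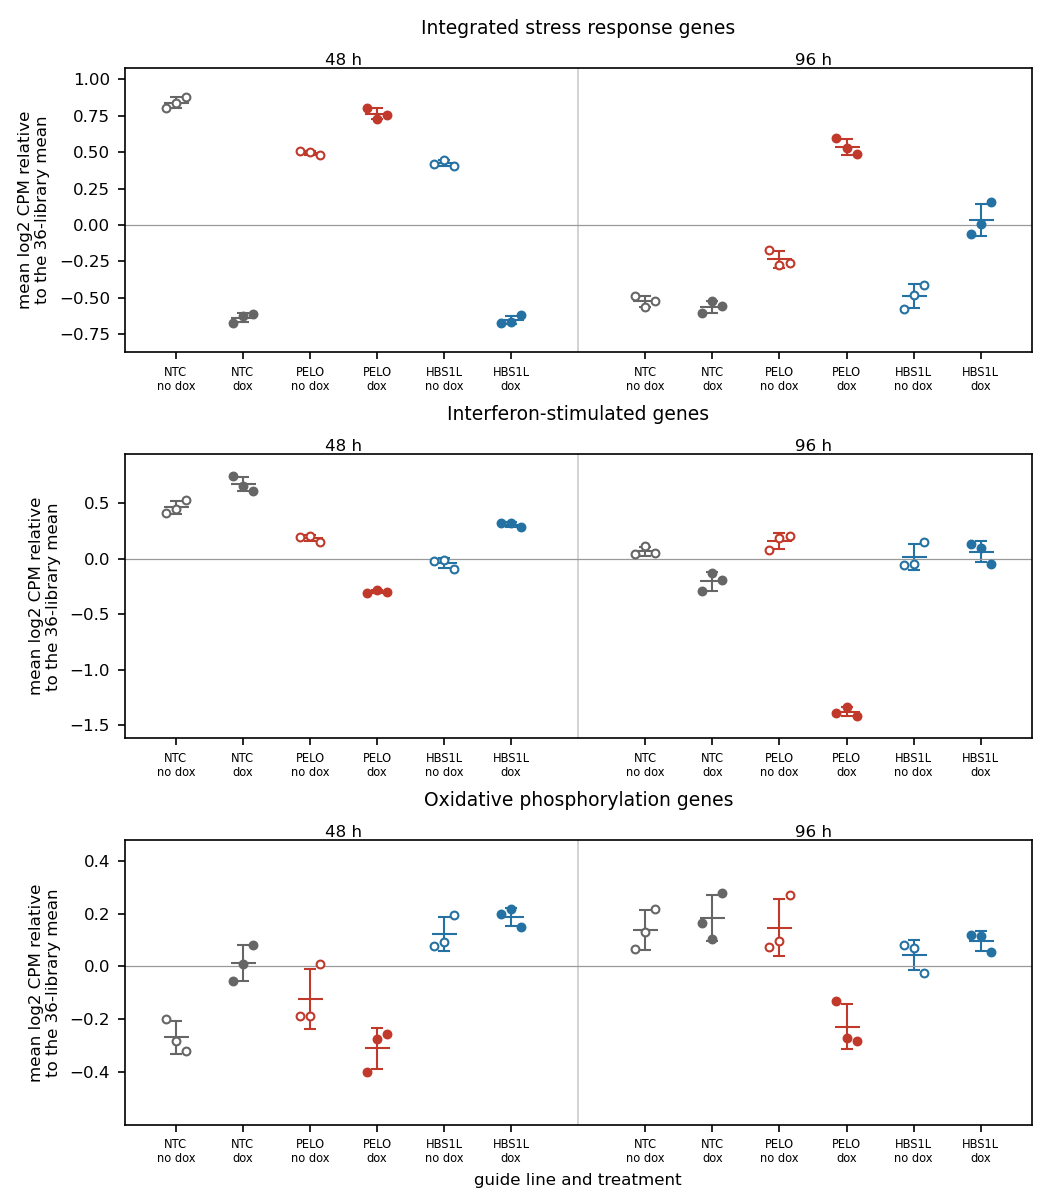
Mean log2 CPM of the integrated stress response, interferon-stimulated and oxidative phosphorylation genes in each library relative to the mean of all 36 libraries, with bars for the mean and SD of 3 libraries. The control line falls from 0.839 to -0.637 in the integrated stress response genes with dox at 48 h, while the PELO line goes from 0.497 to 0.764.

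A large share of the transcriptome changed in the PELO line beyond the control line at 48 h. Stress genes that were lower with dox in the other lines stayed high in the PELO line, and p53 targets rose. NF-kB targets and genes of the BCL2 family and apoptosis were higher beyond the control line, in which both lists fell. Host genes of small nucleolar RNAs rose with the preset correlation only (adjusted p = 0.139 with an estimated correlation). Genes of respiration, cholesterol synthesis and the interferon response were lower, and DNA replication genes rose less than in the control line, again with the preset correlation only (adjusted p = 0.414, 0.179, 0.119 and 0.182 with an estimated correlation). Beyond the control line 9939 genes changed, 4766 up and 5173 down, of which 1035 and 996 changed at least 2-fold. Of these genes, 92.2% also differed in the same direction between the dox libraries of both lines alone.

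The integrated stress response led the rises at 48 h: 39 of 40 genes rose and 1 fell beyond the control line (median log2 change 1.49), and the list held with an estimated correlation (adjusted p = 0.0150). Within the PELO line the median was 0.059, with 16 genes up and 9 down, so much of the difference lay in the fall of these genes in the control line. TRIB3 went from 204.2 ± 4.83 to 318.5 ± 5.41 CPM with dox in the PELO line (log2 change beyond the control line 3.14 ± 0.08, adjusted p = 2.72e-26), CEBPB from 112.9 to 204.4 CPM and INHBE from 7.36 to 16.4 CPM. FGF21, a hormone induced by ATF4, stood at 0.820 CPM without and 1.34 CPM with dox, against 1.96 and 0.0813 CPM in the control line. XBP1, which drives the unfolded protein response, went from 160.3 to 303.9 CPM, though its list as a whole did not pass (13 up, 9 down). GTPBP2, a GTPase gene tied to ribosome rescue, went from 83.7 to 145.4 CPM, and ATF5, tied to mitochondrial stress, from 276.5 to 383.9 CPM. VEGFA rose from 119.5 to 152.1 CPM.

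Damage genes rose at 48 h, and NF-kB targets were higher beyond the control line. GADD45A, which links stress to growth arrest, went from 76.8 ± 4.82 to 697.8 ± 53.3 CPM while it fell from 88.9 to 30.6 CPM in the control line (log2 change 4.72 ± 0.10, adjusted p = 7.95e-27). The p53 targets AEN, an exonuclease gene, and PHLDA3, which restrains AKT, went from 24.7 to 106.1 CPM and from 4.50 to 22.2 CPM. Of 27 p53 targets 20 rose and 5 fell (adjusted p = 0.0112 with an estimated correlation). NF-kB targets had 18 of 27 genes up and 3 down beyond the control line (adjusted p = 0.0163 with an estimated correlation). Their mean level went from 0.383 to 0.492 (log2) in the PELO line and from 0.375 to -0.295 in the control line, so most of this lay in the fall of the control line. The neutrophil attractant CXCL5 went from 37.6 to 95.7 CPM, and RELB and NFKB2 rose by 1.72 and 1.25 on the log2 scale beyond the control line. In the BCL2 family 14 of 25 genes were up and 4 down beyond the control line (adjusted p = 0.0150 with an estimated correlation), with the death promoter BBC3 at 1.62, the death receptor TNFRSF10B at 1.28 and the survival gene BCL2L1 at 1.19. Most of the value of BBC3 lay in its fall in the control line, given above. Immediate early genes were higher beyond the control line (18 up, 3 down; adjusted p = 0.0569 with an estimated correlation), with the transcription factors KLF6 going from 249.1 to 716.3 CPM and KLF4 from 28.6 to 48.4 CPM, and the phosphatase DUSP5 from 21.5 to 65.5 CPM. AREG, a growth factor of the RAS-MAPK list (8 up, 4 down, list not past 0.05), went from 116.6 to 183.7 CPM.

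RNA and ribosome pathways rose at 48 h in several lists. Host genes of snoRNAs, whose spliced transcripts are removed by nonsense-mediated decay, had 14 of 17 up and 2 down (median 1.41; adjusted p = 0.139 with an estimated correlation). ZFAS1 went from 57.0 to 196.9 CPM, SNHG1 from 77.3 to 210.6 CPM and SNHG17 from 20.8 to 63.6 CPM. Nonsense-mediated decay factors had 9 of 14 up and 0 down (adjusted p = 0.327 with an estimated correlation), with SMG5 going from 83.5 to 141.1 CPM, SMG9 from 17.6 to 28.4 CPM and UPF3A from 28.1 to 38.7 CPM. Ribosome biogenesis genes had 20 of 32 up and 2 down (adjusted p = 0.10 with an estimated correlation), among them the helicase gene DDX21 (log2 change 0.91), RRP12 (0.95) and NOP2 (0.89). Translation factors rose in 13 of 36 and fell in 5, or 6 adjusted over the list alone (adjusted p = 0.601 with an estimated correlation). EIF5, which helps ribosomes choose the start codon, went from 224.3 to 687.0 CPM, EIF4G2 from 735.4 to 990.0 CPM, and EIF4EBP1 from 107.5 to 106.1 CPM against 135.6 to 63.6 CPM in the control line. Autophagy genes rose in 16 of 36 and fell in 5, with 17 up adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). They included MAP1LC3B, a coat gene of autophagosomes (1.89), WIPI1 (2.14) and the lysosomal regulator TFE3 (1.38). NRF2 targets had 13 up and 7 down (adjusted p = 0.322 with an estimated correlation), with NFE2L2 itself at 1.38, MAFG at 1.29 and SRXN1 at 1.09. Mitosis genes had 17 up and 3 down (adjusted p = 0.629 with an estimated correlation), with the spindle genes TPX2 going from 347.1 to 620.9 CPM, AURKA from 138.8 to 227.4 CPM and CENPA from 37.5 to 64.2 CPM.

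Respiration, replication and antiviral genes were lower beyond the control line at 48 h. Nuclear-encoded oxidative phosphorylation genes had 69 of 75 down and 0 up (71 down adjusted over the list alone; median -0.44; adjusted p = 0.414 with an estimated correlation). NDUFB4 of complex I went from 67.1 to 54.1 CPM, SDHA of complex II from 154.2 to 126.5 CPM and ATP5MC1 of the ATP synthase from 48.5 to 41.0 CPM, while each rose in the control line. Mitochondrial ribosomal protein genes had 29 of 78 down and 8 up (adjusted p = 0.845 with an estimated correlation), but 25 down and 17 up between dox libraries alone (adjusted p = 0.536), with MRPS27 at a log2 change of -0.51, MRPL19 at -0.56 and MRPL16 at -0.56. Interferon-stimulated genes had 25 of 35 down and 2 up (median -0.77; adjusted p = 0.119 with an estimated correlation). IFIT1, a sensor of viral RNA caps, fell from 31.0 to 17.0 CPM, IFIT2 from 89.3 to 55.7 CPM and BST2 from 11.9 to 4.84 CPM. DNA replication genes had 31 of 37 down and 1 up beyond the control line (32 down adjusted over the list alone; adjusted p = 0.182 with an estimated correlation). Between dox libraries alone they had 20 down and 3 up. Their mean level rose in both lines, from -0.290 to -0.0784 (log2) in the PELO line and from -0.613 to 0.0459 in the control line. The sliding clamp gene PCNA went from 96.1 to 102.0 CPM against 61.6 to 136.4 CPM in the control line, and the polymerase genes POLD1 and POLE2 had log2 changes of -0.79 and -1.02. Cholesterol synthesis genes had 16 of 23 down and 1 up (adjusted p = 0.179 with an estimated correlation), with INSIG1, a sterol sensor partner, falling from 59.2 to 26.5 CPM, and HSD17B7 and ACAT2 at log2 changes of -1.18 and -0.81. Endothelial markers, read here as a check for other cell types, had 3 of 4 down (adjusted p = 0.143 with an estimated correlation): ENG, CDH5 and EMCN had log2 changes of -0.55, -1.74 and -1.38.

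The largest rises at 48 h were in KLHDC7B (log2 change 5.87), L3MBTL2-AS1 (5.80), FGF21 (5.29), the sulfotransferase gene CHST1 (4.96, from 0.757 to 11.7 CPM), the lysosomal membrane gene LAMP3 (4.88) and GADD45A. The largest falls were in LRG1 (-2.58), the junction gene TJP3 (-2.50), ENSG00000287864 (-2.40), CDC42EP5 (-2.20), LRRC4B (-2.00) and RAB3A (-1.98). Among lists that did not pass 0.05 at 48 h, ribosome rescue and ribosome quality control had 10 genes up and 4 down, and the SKI complex with the exosome 6 up and 5 down. Cytosolic ribosomal proteins had 5 up and 3 down (2 up and 3 down adjusted over the list alone), with RPL10A rising by 0.39. Histones had 10 up and 9 down (7 down adjusted over the list alone), with H2AC6 at 1.41. Hypoxia and glycolysis genes had 13 up and 14 down, the heat shock response 7 up and 7 down with DNAJB6 at 0.61, the mitochondrial unfolded protein response 5 up and 5 down, and MYC targets 9 up and 8 down with CCND2 at 3.14. Mitochondrially encoded genes had 0 called by edgeR. Epithelial markers had 3 up and 1 down with CLDN4 at 1.02, fibroblast markers 2 up and 3 down with COL1A2 at -1.27, and leukocyte markers 1 up and 3 down with CD14 at -1.93. Exons of CEBPB, PHLDA3, ZFAS1, NOP2, ACAT2, ATF5, WIPI1, NFE2L2, SRXN1, BCL2L1, CCND2 and L3MBTL2-AS1 overlap another gene over 11.8% to 85.0% of their length, which makes their values less certain.

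By 96 h the PELO response had widened. The p53 targets stayed up, the only list here that also held with an estimated correlation (adjusted p = 0.0448). With the preset correlation only, unfolded protein response genes rose, and interferon-stimulated and cholesterol synthesis genes had lower medians than at 48 h (adjusted p = 0.0951, 0.0514 and 0.0807 with an estimated correlation). Genes of respiration and DNA replication stayed lower, and mitosis genes were down (adjusted p = 0.505, 0.379 and 0.690 with an estimated correlation). Beyond the control line 11376 genes changed, 5967 up and 5409 down, of which 1673 and 1660 changed at least 2-fold. The control line itself changed little at this time, and 90.8% of the genes also differed in the same direction between the dox libraries alone.

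Damage and stress genes were among the rises at 96 h. GADD45A went from 30.7 ± 3.74 to 867.7 ± 29.1 CPM (log2 change 4.63 ± 0.11, adjusted p = 1.13e-26), AEN from 24.6 to 137.2 CPM and PHLDA3 rose by 2.90 on the log2 scale, and 20 of 27 p53 targets rose and 6 fell (21 rose adjusted over the list alone; adjusted p = 0.0448 with an estimated correlation). The integrated stress response had 28 of 40 genes up and 5 down (29 up adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), and here the rise lay within the PELO line (median 0.56). PPP1R15A, which reverses the block of translation, went from 47.7 to 324.0 CPM, CEBPB from 68.8 to 308.5 CPM and the amino acid carrier SLC3A2 from 165.5 to 608.7 CPM. The unfolded protein response had 21 of 29 up and 4 down (adjusted p = 0.0951 with an estimated correlation): the chaperone HSPA5 went from 821.6 to 1921 CPM, XBP1 went from 94.1 to 305.4 CPM, and DNAJB9 rose by 1.90 on the log2 scale. NF-kB targets had 16 up and 7 down (adjusted p = 0.254 with an estimated correlation), but 13 up and 12 down between dox libraries alone (adjusted p = 0.453), with CXCL5 going from 27.5 to 145.0 CPM, NFKBIB from 16.9 to 57.9 CPM and LIF from 51.2 to 132.6 CPM. Immediate early genes had 17 up and 6 down (adjusted p = 0.175 with an estimated correlation), with KLF6, KLF4 and DUSP5 at log2 changes of 1.52, 1.82 and 2.22. The BCL2 family had 13 up and 4 down (14 up adjusted over the list alone; adjusted p = 0.0783 with an estimated correlation), with BIRC2 at 1.22, the death promoter PMAIP1 at 1.94 and BCL2L1 at 0.88. Autophagy genes had 21 up and 7 down (adjusted p = 0.273 with an estimated correlation), led by WIPI1 (2.23), SQSTM1 (1.12) and MAP1LC3B (1.21).

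Several ribosome and RNA lists were higher at 96 h. Ribosome biogenesis had 26 of 32 genes up and 1 down (median 0.68; adjusted p = 0.0605 with an estimated correlation): PNO1 went from 54.7 to 178.2 CPM, NOP58 from 114.4 to 325.1 CPM and RRP9 from 55.9 to 145.0 CPM. The snoRNA host genes had 13 up and 3 down (adjusted p = 0.272 with an estimated correlation), with ZFAS1 going from 56.4 to 365.5 CPM, GAS5 from 187.5 to 828.9 CPM and SNHG1 from 48.0 to 172.8 CPM. Nonsense-mediated decay factors had 11 up and 0 down (adjusted p = 0.293 with an estimated correlation), but did not pass between dox libraries alone (7 up, 0 down; adjusted p = 0.0931), with SMG5, RBM8A and UPF3A at 1.17, 0.61 and 1.05. ZNF598, which marks collided ribosomes, went from 67.8 to 154.8 CPM, in a rescue list with 9 up and 8 down, or 9 down adjusted over the list alone. DIS3L, a catalytic gene of the cytoplasmic exosome, went from 33.0 to 51.9 CPM, in a list with 10 up and 4 down. EIF5 went from 406.0 to 1032 CPM, with 14 translation factors up and 7 down.

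Antiviral, sterol, respiration and keratin genes were among the falls at 96 h. Interferon-stimulated genes had 28 of 35 down and 1 up (median -1.23; adjusted p = 0.0514 with an estimated correlation), with IFIT1 falling from 41.0 to 4.09 CPM, IFITM1, which blocks viral entry, from 137.9 to 14.4 CPM, and BST2 from 9.83 to 0.644 CPM. Cholesterol synthesis genes had 18 of 23 down and 2 up (median -0.82; adjusted p = 0.0807 with an estimated correlation): INSIG1 fell from 68.4 to 18.8 CPM and HSD17B7 from 29.4 to 10.7 CPM. Nuclear-encoded oxidative phosphorylation genes had 57 of 75 down and 1 up (61 down and 2 up adjusted over the list alone; adjusted p = 0.505 with an estimated correlation), with SDHA going from 183.9 to 100.6 CPM, NDUFS7 from 76.5 to 38.0 CPM and NDUFV1 from 141.7 to 77.8 CPM. Mitochondrially encoded genes had 9 of 13 down (10 adjusted over the list alone; adjusted p = 0.673 with an estimated correlation), but 1 down between dox libraries alone (adjusted p = 0.889). The untreated control libraries were low and spread in these genes (mean level -0.865 ± 0.583 on the log2 scale, against -0.144 ± 0.0692 in the untreated PELO line). MT-CO3 went from 1966 ± 277 to 1393 ± 159 CPM, against 1282 ± 473 to 1665 ± 164 CPM in the control line, and MT-ND3 and MT-ND4 had log2 changes of -0.65 and -0.84. DNA replication genes had 25 of 37 down and 5 up (26 down adjusted over the list alone; adjusted p = 0.379 with an estimated correlation), with POLD1 falling from 80.3 to 28.9 CPM and the licensing gene CDT1 from 105.9 to 51.2 CPM. Mitosis genes had 20 of 35 down and 4 up (5 up adjusted over the list alone; adjusted p = 0.690 with an estimated correlation), with KIF20A, CCNB2 and MAD2L1 at -1.03, -0.62 and -0.57. The epithelial keratins KRT19, KRT18 and KRT8 fell from 290.2 to 89.4, 1583 to 787.7 and 1504 to 791.1 CPM, in a list with 3 of 7 down (adjusted p = 0.336 with an estimated correlation, and 0.108 between dox libraries alone). Endothelial markers had 3 of 4 down (adjusted p = 0.0699 with an estimated correlation): CDH5 fell from 15.9 to 0.974 CPM, EMCN from 2.47 to 0.447 CPM and ENG from 68.4 to 43.8 CPM. The collagen gene COL1A2 fell from 221.9 to 30.7 CPM.

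Several genes with almost no reads in the untreated PELO line and in the control line were switched on in the PELO line with dox at 96 h. ALOX5AP, which serves leukotriene synthesis, reached 12.3 ± 0.452 CPM, against 0.0306 CPM without dox and at most 0.0863 CPM in the control line, near the floor. LCE1F reached 5.71 CPM, ATP6V0D2, a proton pump subunit gene, 7.34 CPM and the pseudogene ENSG00000215861 4.11 CPM, each from at most 0.165 CPM without dox and in the control line. From levels above the floor, ANKRD1, a YAP target, went from 0.234 to 12.9 CPM and LCN2, which binds iron carriers, from 0.480 to 22.4 CPM. The largest falls were in CREB3L3 (from 5.87 to 0.267 CPM), CDH5, ENSG00000287864 (log2 change -3.97), the adaptor gene GRB7 (from 32.4 to 2.08 CPM), TJP3 (-3.67) and the lipase gene LIPG (-3.51).

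Other lists did not pass at 96 h. Cytosolic ribosomal proteins had 14 genes up and 6 down (9 up and 4 down adjusted over the list alone) with RPL22 at -0.40, and mitochondrial ribosomal proteins 20 up and 25 down with MRPL16 at -0.78. Histones had 15 up and 15 down with H2AC6 at 1.49, and hypoxia and glycolysis genes 13 up and 16 down with the hexokinase gene HK2 going from 67.0 to 314.1 CPM. RAS-MAPK output had 4 up and 5 down with ETV1 falling from 44.7 to 8.94 CPM, the heat shock response 12 up and 7 down with CHORDC1 at 1.48, and the mitochondrial unfolded protein response 8 up and 6 down with ATF5 at 1.53. NRF2 targets had 14 up and 9 down with PIR at -1.65, and MYC targets 10 up and 6 down with NOP56 at 1.05. Fibroblast markers had 3 up and 4 down and leukocyte markers 2 up and 3 down, with CD68 at 0.89. Exons of IFITM1, NDUFS7, KRT18, SQSTM1, PNO1, RBM8A, ZNF598, CD68 and ATP6V0D2 overlap another gene over 10.4% to 81.7% of their length.

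**Figure D3:**
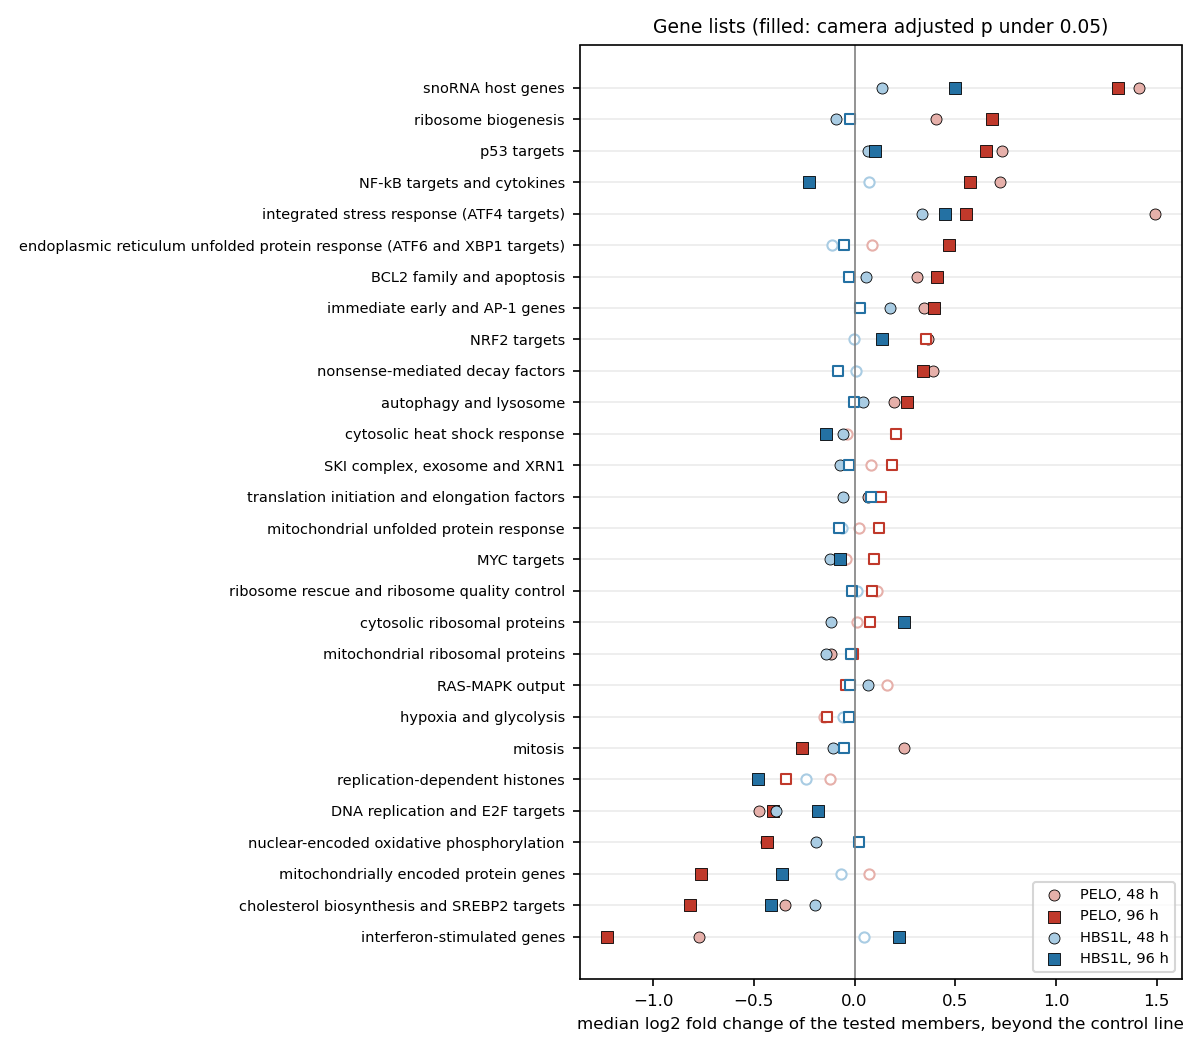
Median log2 fold change beyond the control line of the tested members of each list, for the PELO line and the HBS1L line at 48 h and 96 h, with filled symbols for lists past 0.05 by camera with the preset correlation. In the PELO line the snoRNA host genes stand at 1.41 and 1.31 and the interferon-stimulated genes at -0.77 and -1.23.

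The response of the HBS1L line differed little from that of the control line at 48 h. Most of this difference was not seen between the dox libraries of both lines. Stress and immediate early genes appeared higher and replication genes lower beyond the control line. Beyond the control line 799 genes changed, 292 up and 507 down, but only 108 of them (13.5%) also differed in the same direction between the dox libraries of both lines, and 176 differed in the opposite direction. The count was 512 without replicate 3 of the control line without dox and 484 without its replicate 3 with dox.

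HBS1L itself was the largest fall at 48 h. The integrated stress response had 28 of 40 genes up and 0 down (37 up adjusted over the list alone; adjusted p = 0.0107 with an estimated correlation), with GDF15, a stress hormone, going from 44.5 to 13.4 CPM against 82.9 to 12.3 CPM in the control line. NUPR1 and PHGDH, of which the second starts serine synthesis, had log2 changes of 1.04 and 0.43. Between dox libraries alone the list had 5 up and 6 down (median -0.0063). The DNA replication list had 31 of 37 down and 0 up (34 down adjusted over the list alone; adjusted p = 0.00605 with an estimated correlation), with PCNA, MCM4 and E2F1 at -0.82, -0.53 and -0.57, and between dox libraries alone it had 11 up and 2 down. Immediate early genes had 11 up and 0 down (14 up adjusted over the list alone; adjusted p = 0.00809 with an estimated correlation), and between dox libraries alone the list had 19 up and 2 down (median 0.23). EGR1 went from 237.0 to 315.5 CPM against 244.0 to 221.5 CPM in the control line, NR4A1 from 5.55 to 9.54 CPM against 4.75 to 4.28 CPM, and IER3 had a log2 change of 0.64. Cholesterol synthesis genes had 7 down and 0 up (11 down adjusted over the list alone; adjusted p = 0.0595 with an estimated correlation), led by HSD17B7 (-0.54), INSIG1 (-0.37) and IDI1 (-0.34). Oxidative phosphorylation genes had 8 down and 0 up (30 down adjusted over the list alone; adjusted p = 0.336 with an estimated correlation), led by NDUFB3 (-0.53). Between dox libraries alone the cholesterol list did not pass (adjusted p = 0.249) and the oxidative phosphorylation list had 35 up and 1 down. VEGFA (0.60), ATF5 (0.54) and the histone gene H1-2 (-0.66) were named from further lists. The largest rises were in FUT1 (1.57), the netrin receptor gene UNC5B (1.54), KLHDC7B (1.46), NIBAN1 (1.37), KIF21B (1.10) and NUPR1, and the largest falls after HBS1L in APLN (-1.21), FAM111B (-0.86), PCNA, CCNE2 (-0.82) and POLE2 (-0.68). Of 56 named genes, 33 had the opposite sign between dox libraries alone.

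Smaller shifts of the HBS1L line at 48 h reached 0.05 only with the preset correlation. With an estimated correlation the p53 targets (5 up, 0 down; led by BBC3 at 0.41) had adjusted p = 0.106, the SKI complex with the exosome (0 up, 2 down) 0.0605, mitochondrial ribosomal proteins (0 up, 7 down) 0.441, cytosolic ribosomal proteins (0 up, 0 down) 0.667 and snoRNA host genes (2 up, 0 down) 0.528. Translation factors (1 up, 2 down; EIF4A2 at -0.32) had 0.569, ribosome biogenesis (0 up, 0 down) 0.338, mitosis (0 up, 6 down; PTTG1 at -0.35) 0.477 and RAS-MAPK output (3 up, 0 down) 0.301. Heat shock genes (0 up, 3 down; HSP90AA1 at -0.31) had 0.483, autophagy genes (6 up, 1 down; MAP1LC3B at 0.37) 0.236, the BCL2 family (3 up, 0 down) 0.172 and MYC targets (1 up, 1 down) 0.307. The medians of these lists lay between -0.14 and 0.14. Between dox libraries alone only the snoRNA host genes passed in the same direction. Interferon-stimulated genes had 0 up and 0 down, and NF-kB targets 1 up and 0 down.

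By 96 h the HBS1L response stood out from both the control line and its own untreated cells. Integrated stress response genes rose, while cholesterol synthesis genes and the polyadenylated messengers of histones fell. The snoRNA host genes and cytosolic ribosomal proteins rose with the preset correlation only (adjusted p = 0.0611 and 0.387 with an estimated correlation). Beyond the control line 2228 genes changed, 1123 up and 1105 down, with 115 and 39 changed at least 2-fold, and 95.5% of them also differed in the same direction between dox libraries alone. The count was 1404 without replicate 2 of the control line without dox, 1391 without replicate 2 of the HBS1L line without dox, and 1484 without replicate 2 of the HBS1L line with dox.

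The integrated stress response had 29 of 40 genes up and 0 down at 96 h (32 up and 1 down adjusted over the list alone; adjusted p = 0.0188 with an estimated correlation). PHGDH went from 109.3 ± 4.14 to 211.4 ± 7.65 CPM (log2 change 1.04 ± 0.06, adjusted p = 1.27e-14), the asparagine synthetase ASNS from 55.9 to 112.0 CPM and TRIB3 from 62.4 to 119.4 CPM. ATF5 went from 123.5 to 218.7 CPM, VEGFA from 44.3 to 76.1 CPM, and GDF15 rose by 1.52 on the log2 scale. The snoRNA host genes had 12 of 17 up and 0 down (14 up adjusted over the list alone; adjusted p = 0.0611 with an estimated correlation), with ZFAS1 going from 42.4 to 99.1 CPM, SNHG32 from 70.2 to 144.8 CPM and GAS5 from 151.4 to 258.0 CPM. Cytosolic ribosomal proteins had 33 of 79 up and 0 down (50 up adjusted over the list alone; median 0.25; adjusted p = 0.387 with an estimated correlation), with RPL12 going from 1171 to 1726 CPM, RPL11 from 601.5 to 722.3 CPM and RPS24 from 637.1 to 769.4 CPM. The p53 targets had 7 up and 0 down (10 up adjusted over the list alone; adjusted p = 0.145 with an estimated correlation), with the electron carrier gene FDXR at 0.85, PHLDA3 at 1.05 and the cell cycle inhibitor CDKN1A at 1.02. NRF2 targets had 10 up and 0 down (11 up and 2 down adjusted over the list alone; adjusted p = 0.140 with an estimated correlation), with the ferritin gene FTH1 at 0.62 and AKR1C1 and AKR1C2 at 0.65 and 0.60. Interferon-stimulated genes had 6 up and 1 down (9 up and 2 down adjusted over the list alone), with BST2 at 0.49, OASL at 1.08 and IFI44 at 1.94. This list had adjusted p = 0.486 with an estimated correlation, and 0.0723 between dox libraries alone. Its mean level went from 0.0137 ± 0.115 to 0.0615 ± 0.0957 (log2) within the HBS1L line. In the control line it went from 0.066 to -0.205, so most of the difference lay in the fall of the control line.

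Cholesterol synthesis genes had 20 of 23 down and 0 up at 96 h (21 down and 1 up adjusted over the list alone; adjusted p = 0.00393 with an estimated correlation). INSIG1 fell from 83.8 to 48.2 CPM, LSS, which closes the sterol rings, from 186.2 to 110.9 CPM and IDI1 from 62.3 to 42.5 CPM. Histones had 17 of 59 down and 0 up (19 down adjusted over the list alone; adjusted p = 0.0229 with an estimated correlation), with the linker gene H1-2 falling from 41.9 to 27.6 CPM and the paralogs H2AC18 and H2AC19 at -0.58 each. DNA replication genes had 13 down and 0 up (20 down adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), among them MCM3 and GINS1 at -0.45 and -0.36. NF-kB targets had 8 down and 2 up (12 down adjusted over the list alone; adjusted p = 0.0605 with an estimated correlation), led by BIRC3 (-0.65), TNFAIP3 (-0.80) and NFKB1 (-0.31). Heat shock genes had 4 down and 0 up (12 down adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), among them HSPA1A at -0.42. MYC targets had 3 down (adjusted p = 0.528 with an estimated correlation), with the transferrin receptor TFRC at -0.48. The largest rises were in the keratin gene KRT81 (2.02, from 0.994 to 4.67 CPM), UNC5B (from 6.16 to 21.9 CPM), PRODH (1.58), SYTL1 (1.57), S100A2 (1.56) and GDF15. The largest falls were in IL21R (-1.82), HBS1L, PIK3CG (-1.76), H1-5 (-1.43) and the microRNA genes ENSG00000277437 (-1.37) and ENSG00000264063 (-1.29). Exons of ASNS, SNHG32, FTH1, ATF5, PHLDA3, ZFAS1, IDI1 and IL21R overlap another gene over 14.8% to 62.4% of their length.

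**Figure D4:**
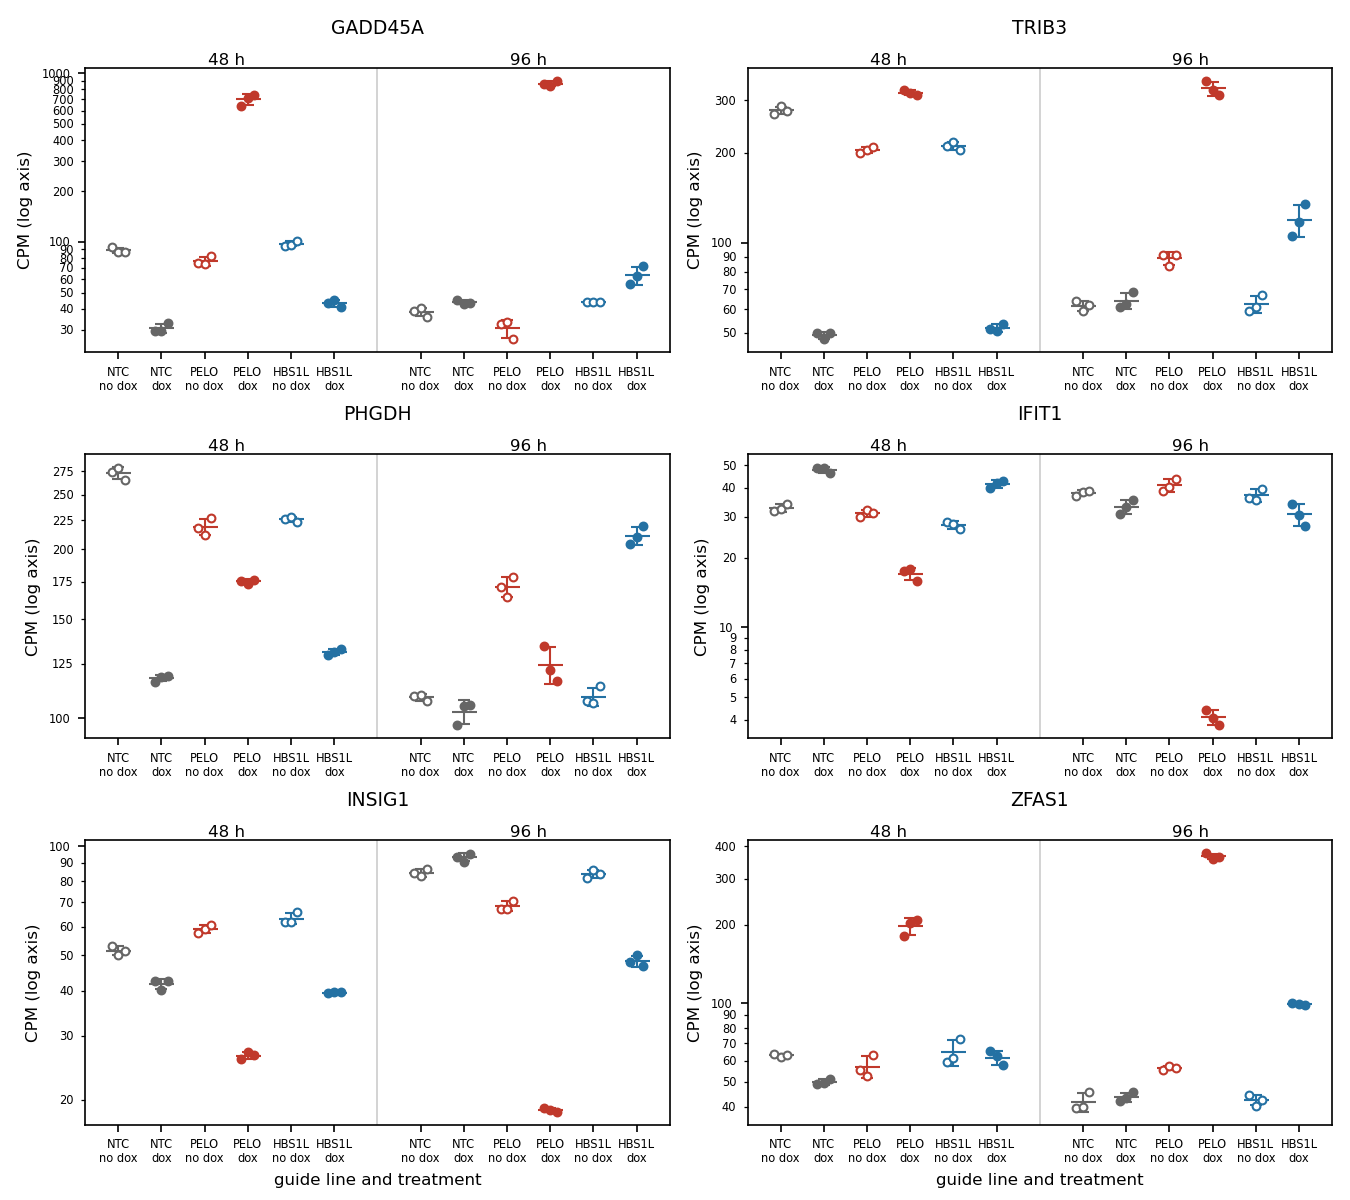
Levels in CPM on log axes of GADD45A, TRIB3, PHGDH, IFIT1, INSIG1 and ZFAS1 in each library, with bars for the mean and SD of 3 libraries. At 96 h dox takes GADD45A from 30.7 to 867.7 CPM in the PELO line, and PHGDH from 109.3 to 211.4 CPM in the HBS1L line.

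The PELO and HBS1L responses differed at many genes. The PELO response was higher than the HBS1L response in p53 targets, NF-kB targets and ribosome biogenesis at 48 h, and lower in interferon-stimulated genes at 96 h. For NF-kB targets most of this lay in the fall of the HBS1L line with dox. At 96 h stress and snoRNA host genes rose and cholesterol genes fell in both lines with the preset correlation. With an estimated correlation these lists had adjusted p = 0.272, 0.272 and 0.0807 in the PELO line, and 0.0188, 0.0611 and 0.00393 in the HBS1L line. The direct contrast, which uses no control library, had 8976 genes at 48 h (4555 higher in the PELO response, 4421 lower) and 11525 at 96 h (6033 higher, 5492 lower).

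At 48 h the PELO response exceeded the HBS1L response in 38 of 40 integrated stress response genes (median 1.04), 19 of 27 p53 targets (0.61), 17 of 27 NF-kB targets (0.79), 21 of 32 ribosome biogenesis genes (0.48) and 11 of 25 BCL2 family genes (0.20). These lists held with an estimated correlation (adjusted p = 0.0229, 0.0107, 0.0150, 0.0448 and 0.0165). The mean level of the stress genes fell from 0.426 to -0.652 (log2) in the HBS1L line and went from 0.497 to 0.764 in the PELO line. For NF-kB targets these were 0.279 to -0.318 and 0.383 to 0.492. In both lists most of the difference thus lay in the fall of the HBS1L line. The p53 targets went from -0.155 to -0.247 in the HBS1L line and from -0.101 to 0.621 in the PELO line. TRIB3 differed by a log2 change of 2.67, CEBPB by 2.04, GADD45A by 4.36, AEN by 2.22, RELB by 1.58, CXCL5 by 1.57, DDX21 by 0.93 and BCL2L1 by 1.07. The interferon list was lower in 27 of 35 genes (median -0.91; adjusted p = 0.0543 with an estimated correlation), with IFIT1 at -1.46 and BST2 at -1.53. At 96 h the interferon list was lower in 29 of 35 and higher in 2 (median -1.55; adjusted p = 0.0378 with an estimated correlation), with IFIT1 at -3.06 and BST2 at -3.72. At 96 h the integrated stress response list had no net difference past 0.05 between the responses. Camera gave adjusted p = 0.123 with the preset and 0.789 with the estimated correlation. Members of the list still differed in both directions, with 18 higher in the PELO response and 10 lower. At that time the unfolded protein response was higher in 23 of 29 genes (adjusted p = 0.0605 with an estimated correlation), with DNAJB9 at 1.80. Cytosolic ribosomal proteins were lower in 36 of 79, or 31 adjusted over the list alone (adjusted p = 0.794 with an estimated correlation), but between dox libraries alone 19 were higher and 11 lower (adjusted p = 0.645), with RPL22 at -0.61 and RPL3 at -0.39. Histones were higher in 24 of 59 (adjusted p = 0.386 with an estimated correlation, and 0.252 between dox libraries alone), with H2AC6 at 1.85, and KRT19 was at -1.87. KCNT2 and CREB3L3 were among the largest falls at 96 h (-4.74 and -4.14), KLHDC7B and INHBE among the largest rises at 48 h (4.41 and 3.87).

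Across the genes tested, which are not independent replicates, the responses within the lines had r = -0.0914 at 48 h and 0.260 at 96 h, with no library in common. At 96 h, 1335 genes rose in both and 938 fell in both, against 782 and 600 for independent calls, and 1052 went opposite ways. The responses beyond the control line share its libraries, which alone gives a correlation: r was 0.450 at 48 h and 0.234 at 96 h, while simulated data with no response gave 0.496 and 0.504. The covariance was 0.124 at 48 h against 0.0442 simulated, and 0.0924 at 96 h against 0.0505. The simulated control line had no dox response, while the real one changed at 7278 genes at 48 h. That change enters both responses and can raise their covariance, so the excess cannot show a response shared by the targeted lines. Within the lines the covariance was -0.0168 at 48 h and 0.0833 at 96 h. At 48 h, 262 genes rose and 384 fell beyond the control line in both, against 67 and 126 for independent calls, and 36 went opposite ways. At 96 h these were 564 and 450 against 323 and 288, with 642 opposite. Calls beyond the same control libraries are not independent, so these overlaps do not measure a response shared by the targeted lines. The control line and the HBS1L line, which share no library, moved together at 48 h (r = 0.550; 3426 genes changed the same way in both and 11 opposite). At 96 h the control line had r = 0.259 with the PELO line, with 1106 genes changed the same way and 210 opposite. With the HBS1L line it had r = 0.156, with 405 the same way and 129 opposite. The r of 0.260 between the targeted lines at 96 h therefore does not show a response particular to them. The PELO response at 48 h and 96 h had r = 0.681, the HBS1L response -0.0470 and the control response -0.0189.

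**Figure D5:**
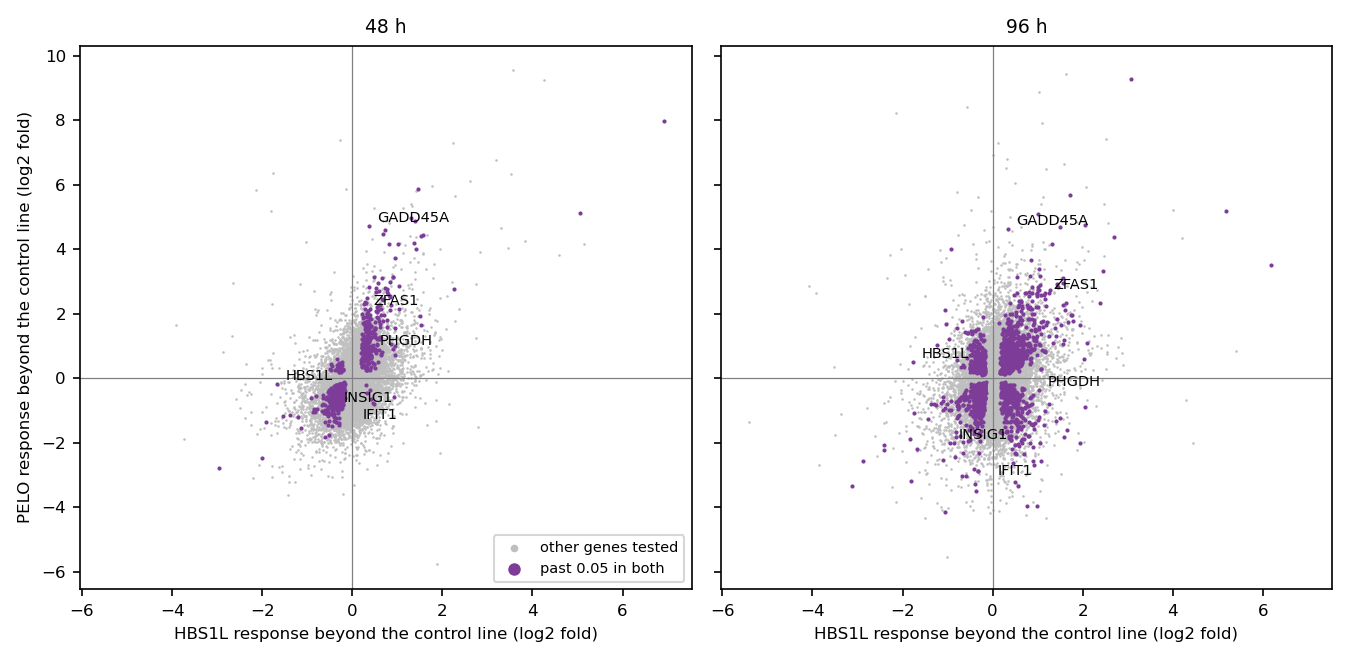
Log2 fold changes beyond the control line of the HBS1L line (horizontal axis) and the PELO line (vertical axis) for each gene tested at 48 h and 96 h, with genes past 0.05 in both in purple. At 96 h, 1014 of the genes past 0.05 in both changed the same way and 642 opposite ways; sharing the control libraries alone gives a positive correlation.

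Each response also changed between the times, in a contrast where time cannot be told apart from library batch. In the PELO line the stress lead over the control line shrank, and epithelial markers dropped. With dox the stress genes of the control line went from 0.839 to -0.637 at 48 h, but only from -0.524 to -0.562 at 96 h. In the PELO line they went from 0.497 to 0.764 at 48 h and from -0.235 to 0.537 at 96 h. The lead thus shrank with the fall of the control line, while the rise within the PELO line was larger at 96 h. In the HBS1L line NF-kB genes moved down, and cytosolic ribosomal protein genes moved up with the preset correlation only (adjusted p = 0.272 with an estimated correlation). The PELO response differed at 4259 genes, 2186 higher and 2073 lower at 96 h, and the HBS1L response at 637, 381 higher and 256 lower.

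In the PELO response 34 of 40 integrated stress response genes were lower at 96 h than at 48 h and 0 higher (35 lower adjusted over the list alone; median -0.73; adjusted p = 0.0187 with an estimated correlation), among them PHGDH (-1.27), MTHFD2 (-1.16) and INHBE (-2.77). Epithelial markers were lower in 4 of 7 (median -0.96; adjusted p = 0.0379 with an estimated correlation), with KRT18 at -1.14 and CLDN4 at -0.88. Mitosis genes were lower in 21 of 35 (24 adjusted over the list alone; adjusted p = 0.208 with an estimated correlation), with CDC25C at -0.99 and CCNB2 at -0.74. Unfolded protein response genes were higher in 18 and lower in 4 (20 and 5 adjusted over the list alone; adjusted p = 0.0940 with an estimated correlation), with SSR1 at 0.62 and PDIA3 at 0.47. In the HBS1L response NF-kB targets were lower in 6 and higher in 1 (9 and 2 adjusted over the list alone; median -0.28; adjusted p = 0.0361 with an estimated correlation), with BIRC3 at -0.68 and TRAF1 at -0.79. Cytosolic ribosomal proteins were higher in 19 of 79 (63 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), with RPL11 at 0.62 and RPS24 at 0.48. The cholesterol list was lower in 9 (15 adjusted over the list alone; adjusted p = 0.0539 with an estimated correlation), with INSIG1 at -0.57, and AKR1C1 was higher by 0.92 and ZFAS1 by 0.89. The count of 637 depended on single libraries. At 48 h it was 316 without replicate 3 of the control line without dox, 422 and 290 without replicates 2 and 3 of the control line with dox, 352 and 368 without replicates 2 and 3 of the HBS1L line without dox, and 389 and 381 without replicates 1 and 3 with dox. At 96 h it was 334 without replicate 2 of the control line without dox, 417 and 408 without replicates 1 and 2 with dox, 362 and 348 without replicates 2 and 3 of the HBS1L line without dox, and 352 and 299 without replicates 1 and 2 with dox.

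The untreated lines were not alike. At 48 h the control cells stood highest in stress genes and lowest in replication genes of the 3 lines, so part of each response beyond the control line reflects where the lines began. At 96 h the HBS1L line matched the control line closely and the PELO line did not. Against the control line without dox the PELO line differed at 2303 genes at 48 h (1322 higher, 981 lower) and 4532 at 96 h (2144 higher, 2388 lower), and the HBS1L line at 7874 (3887 higher, 3987 lower) and 28 (18 higher, 10 lower).

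At 48 h the integrated stress response was lower in 30 of 40 genes in the untreated PELO line (32 adjusted over the list alone; adjusted p = 0.0219 with an estimated correlation), with GDF15 at 43.9 against 82.9 CPM and WARS1 at 629.5 against 848.0 CPM. It was lower in 33 genes in the untreated HBS1L line (34 lower and 1 higher adjusted over the list alone; adjusted p = 0.0710 with an estimated correlation), with SLC7A11 at 39.3 against 83.2 CPM. DNA replication genes were higher in 32 and 33 of 37 genes in the PELO and HBS1L lines (33 and 35 adjusted over the list alone; adjusted p = 0.0107 and 0.0262 with an estimated correlation), with PCNA at 96.1 and 117.6 CPM against 61.6 CPM. The HBS1L line had all 79 cytosolic ribosomal protein genes higher (median 0.31; adjusted p = 0.340 with an estimated correlation), among them RPL23 at a log2 change of 0.39. It had 74 of 75 oxidative phosphorylation genes higher (adjusted p = 0.225 with an estimated correlation), among them ATP5MC1 at 0.72. The BCL2 family was lower in 15 and higher in 3 (adjusted p = 0.0357 with an estimated correlation), with HRK at -0.76. At 96 h the untreated PELO line was lower in 33 of 37 replication genes (34 adjusted over the list alone; adjusted p = 0.0159 with an estimated correlation), with MCM3 at 122.8 against 209.0 CPM. It was higher in 18 of 25 NRF2 targets (19 adjusted over the list alone; adjusted p = 0.00820 with an estimated correlation) and 14 of 19 RAS-MAPK genes (adjusted p = 0.0278 with an estimated correlation), with NQO1 at 751.8 against 518.0 CPM and EGR1 at 83.6 against 55.7 CPM. NF-kB targets were lower in 17 and higher in 2 (18 lower adjusted over the list alone; adjusted p = 0.0361 with an estimated correlation), with BIRC3 at -0.49. Apart from HBS1L, the 28 genes of the HBS1L line at 96 h included CALB2, which binds calcium (32.5 against 56.8 CPM), C15orf48 (-0.87), LAMA4 (1.02) and MYBPH (0.94). That count was 13 without replicate 2 of the control line without dox, 17 and 12 without replicates 1 and 3 of the HBS1L line, and 48 without replicate 3 of the untreated PELO line, which enters only the spread.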

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

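The tests of explanations, the regroupings of libraries and the comparison of the control response between times were chosen only after the results were seen; the refits with 1 library left out, and the comparisons between responses and between times of the PELO and HBS1L responses, were planned.

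Integrated stress response genes were higher in the PELO line beyond the control line at 48 h (median 1.49). A change of the control line alone would leave no difference between the PELO and HBS1L responses, but their contrast had a median of 1.04. That contrast uses no control library, so the control line was not alone in its change. In the HBS1L line the stress genes also fell with dox, from 0.426 to -0.652. The contrast therefore cannot tell an effect of the PELO guide from that fall. Scaling between libraries was excluded, since the list stood 1.53 above the median of all genes tested, a difference that no factor per library can change. A lower stress state of cultures with dox that the PELO line lacked remains open, because the median within the PELO line was 0.059 and no library measures the state of the cultures apart from the guide. The stress genes may therefore have been kept up by the guide or have missed a fall shared by the other lines for another cause.

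Oxidative phosphorylation genes were lower in the PELO line beyond the control line at 96 h (median -0.44), with the preset correlation only (adjusted p = 0.505 with an estimated correlation). Trends on transcript length and GC content did not account for this, with a median of -0.50 after each library's trend on both was removed. Over all genes the fold changes followed length and GC content only weakly (rank correlation 0.0318 and -0.151), so the removal could change little. A change of the control line alone was excluded by a median of -0.39 within the PELO line, and scaling by a difference of -0.454 from the median of all genes tested.

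The HBS1L response beyond the control line at 48 h held 799 genes, of which 13.5% also differed in the same direction between the dox libraries of both lines. A difference between the untreated cultures of the lines goes with this in the stress genes: they stood at 0.839 in the control line and 0.426 in the HBS1L line without dox, and at -0.637 and -0.652 with dox. It was excluded for the immediate early genes, which stood at 0.264 ± 0.0194 and 0.269 ± 0.0359 without dox but at -0.0138 ± 0.0482 and 0.299 ± 0.0360 with dox, a difference of 0.313. For the immediate early genes a change of the control line alone stays open, since their median within the HBS1L line was -0.021. Which of the untreated cultures stood apart was not settled, since ribosomal protein genes were at -0.196 in the control line, -0.134 in the PELO line and 0.124 in the HBS1L line.

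Libraries were regrouped at random to learn how many genes a wrong grouping can give. In comparisons of 3 libraries with 3, only 10 splits exist, too few to exclude chance. The real split and the highest other gave 7586 and 0 genes for dox in the control line at 48 h and 614 and 0 at 96 h, 8879 and 0 and 12720 and 0 in the PELO line, and 5783 and 0 and 4829 and 0 in the HBS1L line. For the untreated lines they gave 1736 and 0 at 48 h and 3039 and 0 at 96 h for the PELO line, and 8136 and 0 and 17 and 2 for the HBS1L line.

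For the other comparisons 100 regroupings over all groups compared were used, the real one included. Mixing libraries of different lines adds their differences to the spread, so such regroupings tend to give few genes. The real grouping gave 9598 genes for PELO beyond the control line at 48 h against 61 in the highest other. For HBS1L it gave 1372 against 593 at 48 h and 2249 against 642 at 96 h. For PELO against HBS1L it gave 8912 against 6614 and 11191 against 9129, and for the change between times 3646 against 2822 (PELO) and 981 against 0 (HBS1L). In each of these only 1 of 100 groupings, the real one, gave as many. For PELO beyond the control line at 96 h, 2 of 100 gave as many: the real one with 10715 genes and another with 10761, so the number of genes does not single out the real grouping there.

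The narrower scheme, which reassigned dox labels only within each line, was run first, and the wider scheme above was adopted after its result was seen. In it, as many genes as the real labels came from 5 of 100 splits for PELO beyond the control line at 96 h (highest other 10916), 5 for HBS1L at 48 h (9104) and 7 for the change of PELO between times (6984), so chance is not excluded for these 3. The scheme gave 3 for HBS1L at 96 h (4119) and 3 for its change between times (4133). It gave 1 for PELO at 48 h (4757), and 1 each for PELO against HBS1L at 48 h (5918) and 96 h (10581). The share was under 0.05 in both schemes for these 5. The wider scheme adds little to this, since it tends to give few genes and was adopted later. Neither scheme can exclude a chance difference between cultures, since the replicates may not be separate cultures. The counts above the real ones, such as 9104 against 1372, came from splits that kept or fully swapped the labels of a line and so retained its dox difference by construction. With no line kept or swapped the highest were 0 for PELO at 96 h, 0 for HBS1L at 48 h and 1 for the change of PELO between times.

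The PELO and HBS1L responses differed at 8976 genes at 48 h and 11525 at 96 h. The PELO response differed between times at 4259 genes, the HBS1L response at 637 (290 to 798 with 1 library left out) and the control response at 5496. At 48 h the PELO response exceeded the HBS1L response by medians of 1.04 in stress genes, 0.61 in p53 targets, 0.79 in NF-kB targets, 0.48 in ribosome biogenesis and 0.20 in the BCL2 family, and at 96 h interferon-stimulated genes differed by -1.55. Most of the difference in stress genes and NF-kB targets at 48 h lay in the fall of the HBS1L line with dox. Between times the PELO response moved by -0.73 in stress genes and -0.96 in epithelial markers, and the HBS1L response by -0.28 in NF-kB targets. Time cannot be told apart from library batch in the last 3 of these.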

How the results depend on the processing

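The comparison of dox libraries alone and the removal of trends on length and GC content were chosen only after results were seen; the other alternatives were planned.

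The larger counts of genes past 0.05 held with the other methods, and the smaller ones moved. For dox in the control line at 96 h, 1561 genes became 614 when only the groups compared were fitted, and 481 to 2141 with 1 library left out. For HBS1L beyond the control line at 48 h, 799 became 1372 with only the groups compared and 484 to 947 with 1 library left out. Between dox libraries alone, another question, 4791 genes differed. For HBS1L at 96 h, 2228 became 1391 to 2424 with 1 library left out, and 6185 genes differed between dox libraries alone. The cause of these shifts was not tested.

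For the change of the HBS1L response between times, 637 genes became 353 with replicate number as a replicate block, 981 with only the groups compared, and 290 to 798 with 1 library left out. With limma-trend on the deposited log2 values 49.2% of the genes past 0.05 were higher, against 59.8%. For the untreated HBS1L line against the control line at 96 h, 28 genes became 95 with no filter, 12 with the stricter filter, 18 with the replicate block, 46 with the DESeq2 Wald test, 17 with only the groups compared, and 12 to 48 with 1 library left out. Libraries of equal replicate number were not more alike: 4 of 18 libraries without dox correlated best with the dox library of their own number.

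Of 576 list tests, 304 passed 0.05 with the preset correlation and 42 with an estimated correlation. The counts were 349 with fry, 234 with the stricter filter, 296 with the replicate block and 295 with trends on length and GC content removed. Over the alternatives, 44714 of 45369 values of named genes kept their call and sign, 615 lost the call, 7 gained it and 33 changed sign. Most of these genes were picked from the same data for small p-values or large changes. Of the values, 37296 came from leaving out 1 library, mostly one outside the comparison, so a high share is largely built in. Apart from the comparison of dox libraries alone, in which 33 of 56 named genes of the HBS1L response at 48 h changed sign, the changes of sign were in PELO messenger RNA, whose log2 change lay near 0. Beyond the control line at 96 h in the PELO line it was 0.01, and became -0.022 with the stricter filter, -0.027 with limma-trend and -0.059 to 0.044 with 1 library left out. It was -0.084 to 0.012 in the HBS1L line at 48 h, and -0.013 to 0.083 for the untreated HBS1L line at 48 h.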

Other observations

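Within the HBS1L line alone, 39 of 40 integrated stress response genes were lower with dox at 48 h and 32 were higher at 96 h, so the same list moved in opposite directions at the times. TRIB3 went from 211.3 to 52.0 CPM at 48 h, much as in the control line, and from 62.4 to 119.4 CPM at 96 h. At 96 h all but 2 of the 79 cytosolic ribosomal protein genes rose within the line (median 0.32; adjusted p = 0.217 with an estimated correlation), and 16 NRF2 targets rose (adjusted p = 0.0107 with an estimated correlation). NIBAN1, a stress gene, went from 23.6 to 89.1 CPM.

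Within the PELO line at 96 h, 31 of 35 interferon-stimulated genes fell and 2 rose (median -1.49; adjusted p = 0.0460 with an estimated correlation). The death ligand TNFSF10 fell from 9.98 to 0.636 CPM, and P2RY6, a nucleotide receptor gene, by 4.08 on the log2 scale.

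Classes of genes were counted without a test of the classes. Of 335 transcribed unprocessed pseudogenes tested in the PELO line beyond the control line, 83 rose and 26 fell at 48 h (median 0.19), and 105 rose and 32 fell at 96 h (median 0.31). Of 1524 antisense genes, 136 rose and 258 fell at 48 h, and 268 rose and 235 fell at 96 h. In the HBS1L line at 96 h antisense genes had 34 up and 7 down.

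Some open points can be settled by measurements not used here. PELO protein, or the sequence at the guide site, would show whether the PELO line lost the gene, which its messenger RNA at 28.3 CPM does not. Libraries of both times made in 1 batch would separate time from batch.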
